A study of Mus musculus with 4 samples.

How the data were processed

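The data were a table of estimated counts per gene for 4 libraries from aortic cells of Wnt1-Cre;Rosa26-mTmG mice, sorted into GFP and tdTomato cells from 1 female sample and from a pool of 2 male samples. Per the labels' protocols, polyadenylated RNA was copied with an oligo(dT) primer and template switching (SMART-Seq v4), amplified by PCR, fragmented with a transposase and read as pairs. This kit does not mark strand, so a gene and its antisense partner cannot be told apart. Per the submitters' processing notes, fastp, HISAT2, StringTie and the mouse build GRCm39 were used, without versions. The program that made the counts and the annotation release were not given in the sources used here. The values the authors deposited were expected counts of reads per gene, that is, estimated counts with up to 2 decimals and not scaled between libraries. Of these, 59.4% to 69.1% were whole (tolerance 1e-06).

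The table held 32948 genes by Ensembl identifier. Symbols came from a reference annotation of an earlier mouse build, matched by identifier for 76.4% of the genes, which held 92.7% to 94.9% of the counts. That annotation was used for names and transcript lengths only, and genome positions were not used here. Every gene list was matched by symbol, and 51 of 380 list members without a match were not analysed here.

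Counts were rounded to whole numbers. Library totals were 13678668, 13911111, 10094167 and 12837085 for female GFP, female tdTomato, male GFP and male tdTomato. Levels are CPM by the library total after TMM scaling (factors 0.922, 1.08, 0.931 and 1.08). Ratios of libraries were log2 with a prior count of 2. Folds of single genes were taken without a prior count and with an exact 95% binomial interval. Against a library at 0 counts the fold was bounded by 3 counts in that library and written as "at least". With PCR and no molecular identifiers, intervals and bounds cover counting error only. Genes entered the tests when edgeR's filterByExpr kept them at a minimum of 10 counts, which left 15055. The filter asks for that level in 2 libraries. Genes seen in 1 library only therefore entered neither the tests nor the numbers of genes 2-fold apart.

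The GFP and tdTomato libraries of a pair hold different cells of the same suspension, so the suspension was a block in the main test, and the 2 pairs were its only replicates. p-values therefore measure the spread between 2 suspensions that also differ in sex. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with 1 residual degree of freedom and Benjamini-Hochberg adjustment at 0.05. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run on the same design. Tested on data simulated from these libraries with 50 genes changed at each of 4 folds among 15055, the edgeR test recovered 48 at 4-fold, 50 at 16-fold and 50 at 64-fold at a dispersion of 0.05, with 7 false calls. At the dispersion of the real libraries, 1.47, it recovered 0 at every fold. Comparisons with 1 library on each side (colours within a sex, and sexes within a colour) have no test, and genes at least 2-fold apart were counted. With 4 libraries for 4 combinations, the sort by sex interaction has none either.

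The following choices were made before the data were examined: the groups, the main tests, the alternatives tried except those named as added later, 29 gene lists, and the rule for naming genes. The lists covered smooth muscle, pericyte, endothelial, fibroblast, immune, glial, pigment, neuronal, adipocyte, erythroid, mesothelial and cardiomyocyte markers, developmental regulators, matrix and signalling pathways, stress, mitochondrial, cell cycle and sex-linked genes. Some genes stood in more than 1 list, among them Sox9 and Notch3. Genes withheld from this text are not reported here, although lists and counts include them. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, over the 23 lists with at least 3 tested members. The estimated correlation rests on 1 residual degree of freedom, and camera then takes its p-value from that 1 degree too. Hardly any list could pass so, and a call lost there does not show that correlation between genes removed it. No list passed with an estimated correlation or with fry. Each list's median was also set among 10000 random lists of the same size matched on mean expression in 20 classes.

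The naming rule took, for the colours, genes past the threshold, or else 10 in each direction by the smaller of the folds in the 2 pairs at 10 CPM or more in both libraries of the higher colour. For the sexes it took 10 in each direction by the smaller of the folds in both colours, and for opposite folds 5 in each direction. Gene models without an approved name were left out. The 3 most abundant tested members of each list were open to naming. Pecam1, Tek, Cdh5, Des, Pdgfra, Pi16, Col14a1, Hoxb2, Tbx20 and the marker genes plotted beyond this rule were chosen after their values were seen.

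Alternatives were another scaling (DESeq2's size factors or library totals), other filters, and TMM scaling after the listed mitochondrially encoded genes were dropped. Others were no block, a prior count of 10, a 4-fold rule, and each library left out in turn, with no block. Added after the data were seen were edgeR with its newer dispersion method, with robust estimation, a filter at a mean of 50 CPM, the left-out libraries for the gene lists, and the matched random lists for the pairs.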

Results

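Messenger RNA was profiled in cells of the mouse thoracic aorta (its ascending part and arch) sorted by colour from Wnt1-Cre;Rosa26-mTmG animals. In this reporter strain every cell carries the red membrane protein tdTomato until Cre recombinase acts, after which the cell and its descendants carry green GFP. Wnt1-Cre acts in the neural crest, the embryonic cell population that gives rise to part of the smooth muscle of the arch. A suspension from 1 female sample and a suspension pooled from 2 male samples were each sorted into GFP and tdTomato cells. This gave 4 libraries, 1 for each sex and colour, so no combination was replicated. The submitters labelled all 4 as vascular smooth muscle cells, and the sort they described used the fluorescent proteins alone.

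The libraries held 13678806 estimated counts in female GFP, 13911281 in female tdTomato, 10094326 in male GFP and 12837282 in male tdTomato. Genes with at least 10 counts numbered 12008, 16227, 9517 and 15669 in the same order, so that both GFP libraries detected fewer genes than their tdTomato partners. By counting error alone, a count of 0 allowed levels of up to 0.24, 0.203, 0.323 and 0.218 CPM (counts scaled to library size), the worth of 3 counts in each library. Loss of transcripts before sequencing is not covered by these bounds. Among genes with a mean of at least 10 CPM, 9.44% were at 3 counts or fewer in female GFP and 23.5% in male GFP, against 1.14% and 1.64% in the tdTomato libraries. Across 15055 genes, which are not independent replicates, Pearson's r of log2 CPM was 0.77 between the tdTomato libraries and 0.457 between the GFP libraries, the highest and lowest of 6 such values. The nuclear transcript Malat1 took 9.04% of the counts in male GFP and 4.15% to 4.77% in the other libraries.

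**Figure D1:**
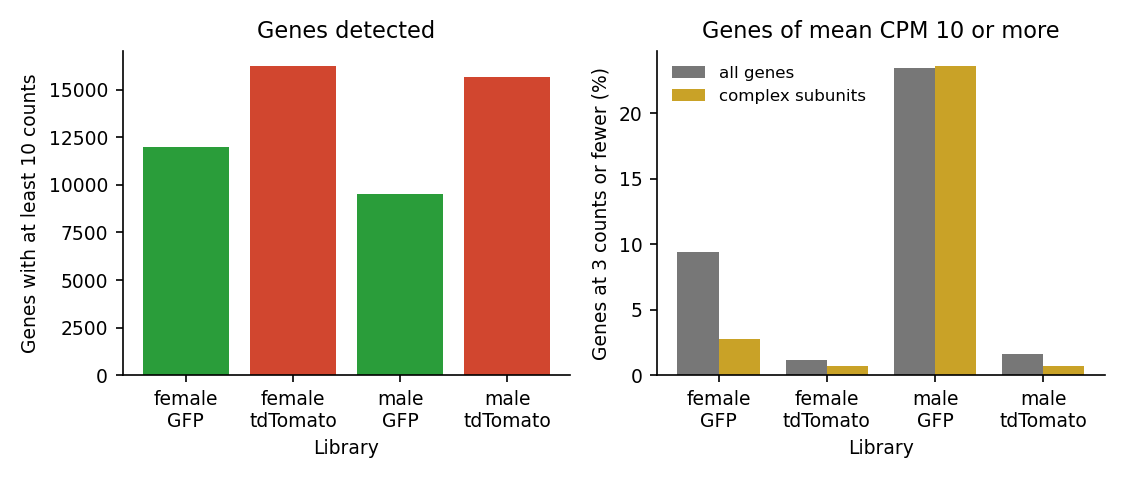
The left panel shows, as bars, the number of genes with at least 10 counts in each of the 4 libraries, 12008 in female GFP and 9517 in male GFP against 16227 and 15669 in tdTomato. The right panel shows the percent of genes at 3 counts or fewer among all genes with a mean of at least 10 CPM (grey) and among 144 subunits of the mitochondrial ribosome, the proteasome, RNA polymerase II and respiratory complex I (gold), 23.5% and 23.6% in male GFP and 9.44% and 2.78% in female GFP.

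The sex labels were checked first with sex-linked genes. Ddx3y, a Y-linked RNA helicase, had 0 counts in both female libraries and levels of 143 CPM in male GFP and 325 CPM in male tdTomato. Eif2s3y, a Y-linked translation initiation factor, had 0 counts and 1 count in the female libraries and 181 and 92.4 CPM in the male ones. Xist, the RNA that coats the inactive X chromosome, stood at 801 and 850 CPM in the female libraries and at 1.40 and 0.145 CPM in the male ones. Tsix is transcribed antisense to Xist, and reads of such a pair cannot be told apart without strand. Uty and Kdm5d were low in all libraries, between 3.76 and 16.5 CPM and between 0.338 and 1.82 CPM, and their counts are uncertain because close X-linked copies can share reads.

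The first comparison set GFP cells against tdTomato cells, that is, cells with a history of Wnt1-Cre against the other cells of the same suspension. The contractile smooth muscle genes Acta2, Myl9 and Tagln were abundant in both fractions, while Des, of the same list, had 56 to 303 counts. Most markers of endothelium and macrophages (13 of 15 and 8 of 10) were at least 2-fold lower in GFP than in tdTomato in both pairs. Acta2, the smooth muscle actin, measured 6807 CPM in GFP and 4940 CPM in tdTomato of the female suspension, and 4124 and 3729 CPM in the male one. Ptprb (ENSMUSG00000020154), a receptor phosphatase of endothelial cells, measured 173 and 127 CPM in the tdTomato libraries, 0.16 CPM in female GFP and 0 in male GFP. Atl1 (ENSMUSG00000021066), which shapes the endoplasmic reticulum, was on the GFP side, at 94.96 and 74.3 CPM against 2.03 and 0.509 CPM. No single gene passed the test over the 2 pairs. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 15055 genes, the smallest adjusted p being 0.577. Unadjusted p was under 0.05 for 1298 genes, 44 higher in GFP and 1254 higher in tdTomato. Evenly spread p-values would give 753, but the same test gave 262 with the libraries divided by sex. It gave 86 with the division that follows neither colour nor sex. DESeq2 called 1157 genes on the same pairs, 49 higher in GFP and 1108 higher in tdTomato, and limma-voom called 0. The spread was wide, with a common dispersion of 1.47, and in data simulated at that spread the edgeR test recovered 0 of 50 genes changed 64-fold.

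The genes named on the GFP side were among those with the largest folds in the pair where the fold was smaller, and none was past the threshold. Atl1 was 46.9-fold higher in GFP in the female pair (95% counting interval 32.6 to 69.8) and 146-fold higher in the male pair (70.5 to 365), a mean log2 ratio of 6.12 ± 0.96 (SD, n = 2 pairs). Its edgeR adjusted p was 0.577. Col11a2, a collagen chain of cartilage, was 20.9-fold and 52.2-fold higher. Pdzrn4 measured 15.7 and 75.9 CPM in GFP against 0.0676 and 0 CPM in tdTomato. Zfp52, Dusp19, Rnf213, Tnfaip8, Oas1c and Cipc were also named, with edgeR adjusted p-values from 0.577 for Zfp52 to 0.757 for Rnf213. Zfp52 and Oas1c belong to families of similar genes, so that their counts are uncertain.

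On the tdTomato side, Ptprb was 1083-fold higher in the female pair (299.6 to 8951) and at least 393-fold higher in the male pair. Its mean log2 ratio of GFP over tdTomato was -9.36 ± 0.39 (SD, n = 2 pairs) with an edgeR adjusted p of 0.577. Heg1, a transmembrane protein of endothelium, measured 248 and 86.2 CPM in tdTomato against 0.08 and 0 CPM in GFP. Ptch1, the receptor for Hedgehog ligands, had 0 counts in both GFP libraries and was at least 351-fold higher in tdTomato in the female pair and at least 268-fold in the male pair. The chemokine Ccl7, at 67.7 and 222 CPM in tdTomato, and the transcription factor Egr3, at 68.4 and 183 CPM, also had 0 counts in both GFP libraries. Mmp3, a matrix metalloprotease, measured 170 and 137 CPM in tdTomato and 0.24 and 0 CPM in GFP. Gng11, Ap3s1, Acyp2 and Fam210a had 0 counts in both GFP libraries and 57.8 to 179 CPM in tdTomato. The bounds on these folds cover counting error and not loss of transcripts. Of all genes at 50 CPM or more in both tdTomato libraries, 0.998% had 0 counts in female GFP and 5.43% in male GFP.

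**Figure D2:**
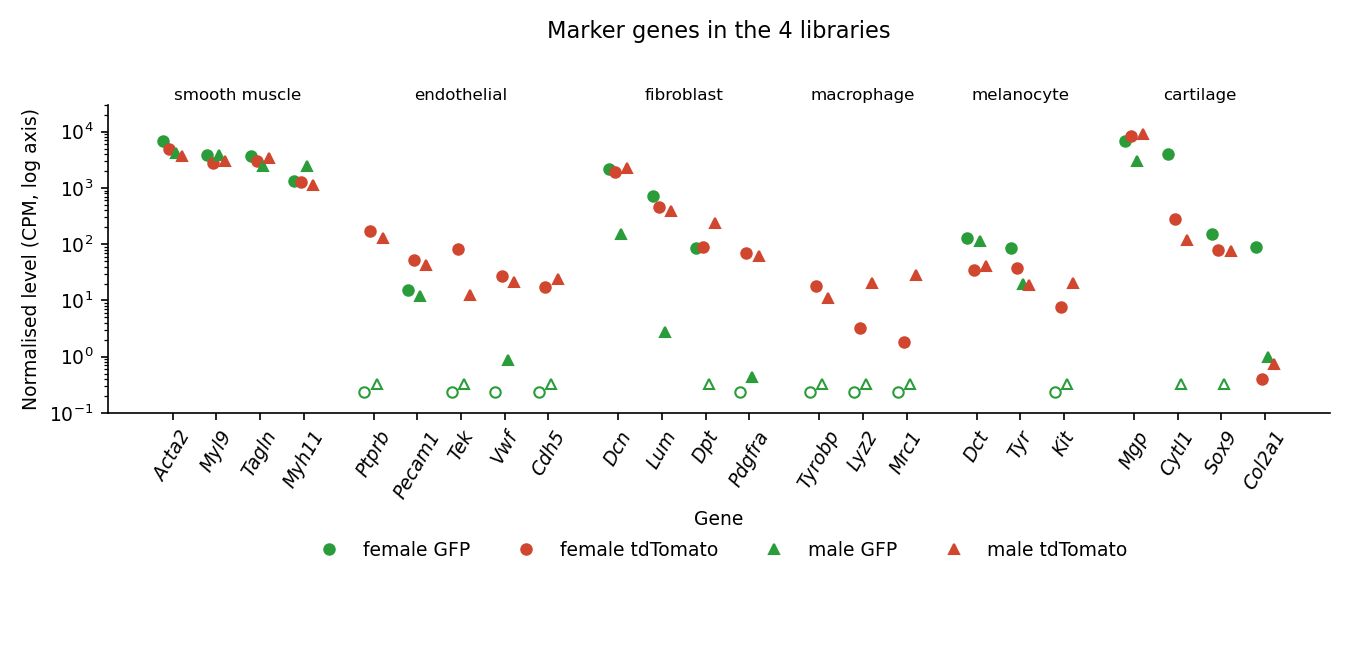
Normalised level (CPM, log axis) of marker genes in the 4 libraries, with GFP in green, tdTomato in red, circles for the female suspension and triangles for the male one. Open symbols stand for 3 counts or fewer and are drawn at the level of 3 counts. Ptprb is at 173 and 127 CPM in tdTomato and open in both GFP libraries, and Lum is at 722 CPM in female GFP and 2.80 CPM in male GFP.

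Blood vessel endothelial genes were lower in GFP as a group. Of the 15 tested, 13 were at least 2-fold lower in GFP in both pairs, the exceptions being Erg and Esam, whereas random lists matched on expression held a median of 5 such genes (95% of them 1 to 8). The list's median log2 ratio was -6.33 in the female pair and -5.53 in the male pair, or -5.94 and -4.60 with genes absent from GFP set at their bound, against -0.73 and -1.52 in matched random lists. Tek, the angiopoietin receptor, measured 81.1 and 12.7 CPM in tdTomato and 0.08 and 0 CPM in GFP, Cdh5 17.6 and 24.1 CPM against 0.08 and 0 CPM, and Pecam1 51.5 and 41.9 CPM against 15.4 and 11.9 CPM. Erg went apart, at 44.9 CPM in female GFP and 555 CPM in male GFP against 58.4 and 60.2 CPM in tdTomato. The camera test over the list gave an adjusted p = 2.69e-05 with a preset correlation between genes and an adjusted p = 0.894 with an estimated correlation. The estimate, -0.067, lay below the preset 0.01, so 1 residual degree of freedom and not correlation removed the call there. Fits with 1 library left out also had no block for suspension. The call was lost without the female GFP library and the block (adjusted p = 0.285), and both GFP libraries, in which the list was low, were those with the fewest genes detected. Of lymphatic endothelial genes, Pdpn and Lyve1 were tested, and both had 0 counts in GFP and 6.49 to 13.7 CPM in tdTomato.

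Macrophage and monocyte genes were lower in GFP in both pairs by at least 2-fold for 8 of 10 members, against 1 to 7 in 95% of matched lists, with medians of -3.83 and -5.22 (log2). These medians were at percentiles 4.55 and 0.62 of matched lists. Mrc1, the mannose receptor, had 0 counts in both GFP libraries and 1.82 and 28.2 CPM in tdTomato. Csf1r, the receptor of the macrophage growth factor, measured 6.48 and 0.108 CPM in GFP against 4.80 and 19.4 CPM. Cd14 was higher in female GFP (24.3 against 8.24 CPM) and lower in male GFP (0.108 against 2.25 CPM). The camera adjusted p = 5.25e-04 was also lost with an estimated correlation (adjusted p = 0.894), and, with no block, without the female GFP library (adjusted p = 0.285) and without the male GFP library (adjusted p = 0.0913). Hox genes, which mark position along the body axis, were at least 2-fold lower in GFP in both pairs for 7 of 9 members (1 to 6 in matched lists), with medians of -4.75 and -3.28. Among matched random lists the female median was at percentile 0.27, the male one at 19.3 and the median over both pairs at 9.39, so only the female one lay outside the middle 95%. Hoxa5 measured 13.3 and 5.27 CPM in GFP against 31.8 and 52.4 CPM in tdTomato, and Hoxb2 had 0 counts in both GFP libraries against 19.8 and 15.5 CPM. Hoxb3 was the exception of opposite sign, at 19.6 and 29.9 CPM in GFP against 41.9 and 15.5 CPM. The Hox list had a camera adjusted p = 0.00475, an adjusted p = 0.894 with an estimated correlation and an adjusted p = 0.412 without the female GFP library and the block.

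Contractile smooth muscle genes were within a few fold of each other in all libraries. Of 18 members, 9 were higher in GFP in both pairs, and none was at least 2-fold higher in both. Only 1, Des, was lower in both, and by at least 2-fold. Myl9, a myosin light chain, measured 3937 and 3845 CPM in GFP against 2778 and 3019 CPM, and Tagln 3760 and 2430 CPM against 3058 and 3440 CPM. The list medians were 0.13 and 0.48 (log2), and the female value was -0.09 when libraries were scaled by their totals. The mean of both pairs was at percentile 79.9 of matched random lists, although the camera test put the list higher in GFP (adjusted p = 3.87e-04, and 0.894 as adjusted p with an estimated correlation). Without the male GFP library and the block its adjusted p = 0.142, and among genes of at least 50 CPM the sign turned (adjusted p = 0.813). Immediate early and heat shock genes, which respond to tissue digestion and other stress, had medians of 0.76 in the female pair and -0.56 in the male pair. Fos measured 13960 and 7907 CPM in GFP against 8377 and 6744 CPM, and Egr1 4434 and 2421 CPM against 2531 and 3740 CPM. Hspa1b measured 5132 and 5506 CPM against 3360 and 3175 CPM, with reads that its near-identical neighbour Hspa1a can share. The list's median over both pairs was 0.12 and its mean -0.01, with a camera adjusted p = 0.0101, an adjusted p = 0.894 with an estimated correlation, and a turned sign without the female GFP library and the block (adjusted p = 0.499).

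Markers of the adventitial fibroblast, the main stromal cell of the outer wall, differed between the GFP libraries in both directions, 10 of 15 being at least 2-fold lower in male GFP than in female GFP and 5 at least 2-fold higher (log2 ratios with a prior count of 2). Dcn, a small proteoglycan, measured 2156 CPM in female GFP and 155 CPM in male GFP, against 1940 and 2258 CPM in tdTomato. Lum measured 722 and 2.80 CPM against 452 and 394 CPM, and Gsn 831 and 313 CPM against 766 and 1187 CPM. Pi16 went the other way, at 10.96 and 89.3 CPM in GFP against 23.8 and 62.1 CPM, as did Col14a1, at 8.08 and 19.03 CPM against 99.9 and 129.8 CPM. The list median was -0.94 in the female pair and -6.72 in the male pair (-5.69 at the bound), and 6 of 15 members were at least 2-fold lower in both, against 0 to 4 in matched lists. The camera adjusted p = 0.0815 did not pass, and passed without the block for suspension (adjusted p = 0.0169) and among genes of at least 50 CPM (adjusted p = 0.00365). Pdgfra, a receptor of fibroblasts, had 0 counts in female GFP and 0.43 CPM in male GFP against 69.3 and 62.5 CPM in tdTomato.

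Genes of glial and pigment cells, both of which derive from the neural crest, did not pass as lists. S100b, of the Schwann cell list, measured 64.6 and 8.39 CPM in GFP against 6.69 and 10.5 CPM in tdTomato. Dct, an enzyme of melanin synthesis, measured 128 and 115 CPM in GFP against 35.5 and 40.2 CPM (mean log2 ratio 1.68 ± 0.24, SD, n = 2 pairs), and Tyr, tyrosinase, 85.4 and 19.2 CPM against 38.4 and 18.8 CPM. Kit, which melanocytes and mast cells carry, measured 0 and 0.215 CPM in GFP against 7.77 and 20.1 CPM. Camera gave an adjusted p = 0.527 for the Schwann list and an adjusted p = 0.938 for the melanocyte list, although the Schwann list's median over both pairs was at percentile 99.5 of matched random lists (97.2 in the female pair and 76.1 in the male pair).

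None of the lists of regulators, matrix, pathway and mitochondrial genes named next passed the main test, but some medians lay low among matched random lists. Over both pairs, collagen, Notch and mitochondrial genes were at percentiles 1.97, 1.31 and 1.45, and the other lists named here at 3.18 to 76.4. Notch and mitochondrial genes were low in the male pair (0.01 and 0.08) and not in the female pair (43.5 and 88.6). Elastic fibre genes were at 0.69 in the female pair and 33.0 in the male pair. These percentiles are not adjusted for the number of lists. Of 12 regulators of the neural crest and pharyngeal arches, Foxc1 measured 182 and 241 CPM in GFP against 277 and 182 CPM, and Prrx1 248 and 0.323 CPM against 262 and 207 CPM (camera adjusted p = 0.673). Of 10 regulators of the second heart field, the mesoderm that also feeds the outflow vessels, Mef2c measured 324 and 208 CPM against 183 and 173 CPM, and Gata6 175 and 118 CPM against 144 and 163 CPM. Tbx20, of the same list, had 0 counts in both GFP libraries against 50.3 and 6.25 CPM (list adjusted p = 0.762). Elastic fibre genes had medians of -0.61 and -0.26, with elastin (Eln) at 525 and 392 CPM in GFP against 748 and 519 CPM (list adjusted p = 0.938). Collagen genes had medians of -0.49 and -0.71, Col1a2 at 652 and 1325 CPM against 1406 and 1428 CPM (list adjusted p = 0.928). Of 17 collagen genes, 9 were lower in GFP in both pairs and 1 was higher in both. The collagen list passed as lower in GFP among genes of at least 50 CPM (adjusted p = 0.00365). In the TGF-beta pathway list, whose median changed sign with the scaling in both pairs, Ccn2 measured 2122 and 3513 CPM against 2222 and 2043 CPM (list adjusted p = 0.672). Notch pathway genes had medians of -0.20 and -6.38, Hes1 at 364 and 190 CPM against 419 and 307 CPM and Jag1 at 190 and 0 CPM against 59.0 and 52.5 CPM (list adjusted p = 0.673). The mitochondrially encoded genes had medians of 0.52 and -1.35, mt-Co2 at 4728 and 1212 CPM against 3337 and 3988 CPM (list adjusted p = 0.562). They passed as lower in GFP among genes of at least 50 CPM (adjusted p = 0.00365) and without female GFP and the block (adjusted p = 0.00102), and as higher in GFP without male GFP and the block (adjusted p = 0.0104).

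The remaining lists had few tested members, no call in the main test and these leading values. Rgs5, of the pericyte list, measured 336 and 1707 CPM in GFP against 500 and 295 CPM (list adjusted p = 0.713). Fabp4, of the adipocyte list, measured 180 and 319 CPM against 228 and 104 CPM (list adjusted p = 0.677), and Ryr2, of the cardiomyocyte list, 43.5 and 156 CPM against 73.3 and 66.1 CPM (list adjusted p = 0.938). Mgp, the calcification inhibitor that led the cartilage and bone list, measured 6881 and 3006 CPM against 8457 and 9286 CPM (list adjusted p = 0.714), and Npr1, of the vasoactive receptors, 68.2 and 41.6 CPM against 58.6 and 69.6 CPM (list adjusted p = 0.714). The Y-linked, X-linked and sex steroid lists had camera adjusted p-values of 0.928, 0.938 and 0.928. Without male tdTomato and the block the tdTomato side was female only, so that Y-linked genes came out higher in GFP through sex. Stmn2, the only neuronal gene tested, measured 23.2 and 20.4 CPM in tdTomato against 0 and 0.108 CPM in GFP. Ms4a1 and Cd3d, of the lymphocyte list, stayed at or below 4.12 CPM, and Cenpf and Birc5, of the cell cycle list, at or below 3.55 CPM. The mesothelial genes Krt18 and Msln measured 46.2 and 0 CPM and 2.48 and 12.4 CPM in GFP, and none of the erythroid genes had enough counts to be tested. Adjusted over the list alone, edgeR called Pdpn and Lyve1 of the lymphatic list and Stmn2 of the neuronal list, each a list of 1 or 2 tested genes, and 0 genes of every other list, as over all genes tested.

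**Figure D3:**
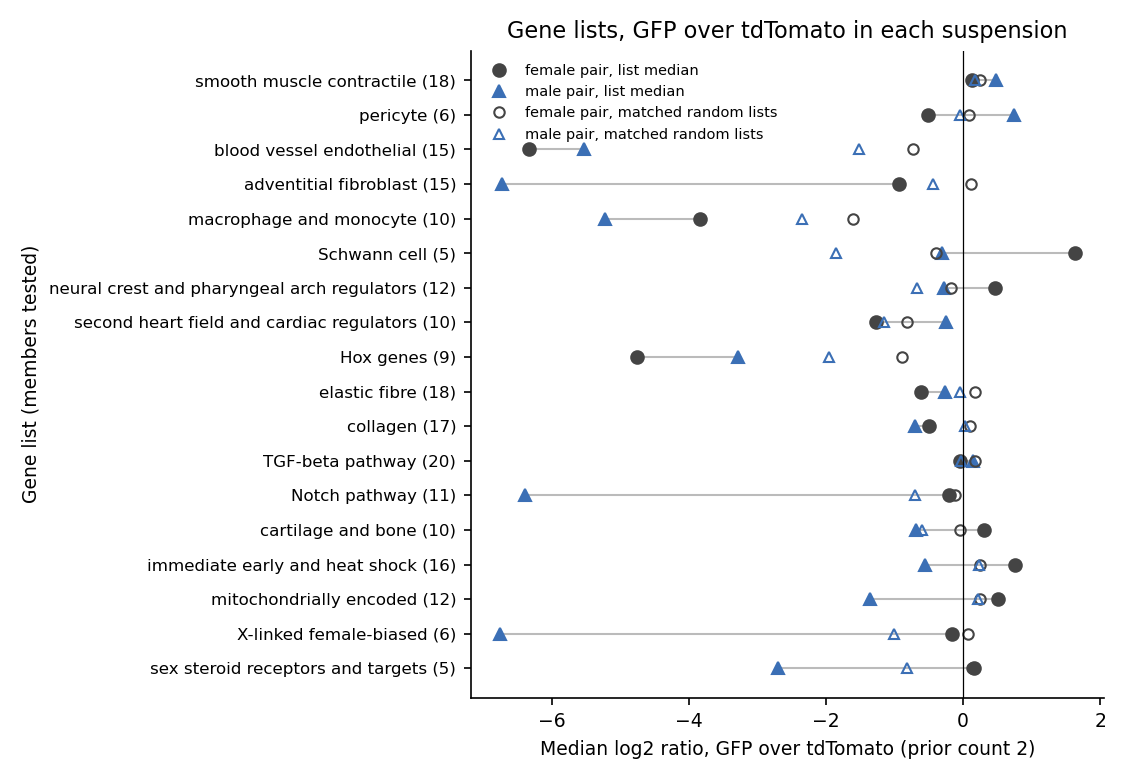
Median log2 ratio of GFP over tdTomato for each list of 5 or more tested genes, with filled circles for the female pair, filled triangles for the male pair and open symbols for the median of matched random lists. Endothelial genes are at -6.33 and -5.53 against -0.73 and -1.52, and fibroblast genes at -0.94 and -6.72.

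Within each suspension, GFP and tdTomato cells were compared without a test, 1 library standing on each side. In the female pair 9008 of 15055 genes were at least 2-fold apart, 3318 higher in GFP and 5690 higher in tdTomato. In the male pair the numbers were 10767, 3244 and 7523. Atl1 and Dct were among 779 genes at least 2-fold higher in GFP in both pairs, against 715 if the pairs were independent, and Ptprb was among 3444 genes lower in both, against 2843. The ratios of the pairs had a Pearson's r of 0.14 and a Spearman's rho of 0.12 across genes. The median gene lay at -0.27 (log2) in the female pair and -0.998 in the male pair, -0.15 and -0.78 with DESeq2's size factors, and -0.48 and -1.20 with library totals, so that list medians were read against matched lists.

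The second comparison set male against female cells within each colour. Apart from the Y-linked genes and Xist, the genes farthest apart in the same direction in both colours were of mixed kinds. Rgs19, a regulator of G protein signalling, measured 326 CPM in male GFP and 14.1 CPM in male tdTomato, with 0 counts in both female libraries. Erbb4, a neuregulin receptor, measured 16.9 and 19.7 CPM in the male libraries and had 0 counts in the female ones. On the female side, B9d1, a protein of the ciliary base, measured 55.1 CPM in GFP and 24.3 CPM in tdTomato with 0 counts in both male libraries, and Leo1, of the Paf1 transcription complex, 30.4 and 19.3 CPM with 0 counts in both. Xist was 573-fold higher in female GFP than in male GFP (335 to 1076) and 5849-fold higher in tdTomato (1619 to 48300). Prr14l, Xlr3b, Far2, Snapc3, Tmem255a and Zfp87 were the other genes named as higher in male, at 16.7 to 154 CPM, and Xlr3b and Zfp87 have similar copies that can share reads. Rbm48, Fbxl7, Myo1e, Zfp518b, Diras2, Sac3d1 and Cox15 were the others named as higher in female, at 15.7 to 97.9 CPM.

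Within a colour 1 library stood on each side, without a test, and sex, animal and digestion cannot be told apart because each sex was a single suspension. Over both colours, with colour as the block, edgeR called 0 genes and DESeq2 140. The colours of a suspension are not independent replicates of a sex, so these calls are no test of sex. Within GFP 10278 genes were at least 2-fold apart (4203 higher in male, 6075 higher in female) and within tdTomato 6349 (3095 and 3254). Both colours had the same direction for 946 genes higher in male, against 864 if independent, and for 1558 higher in female, against 1313. The ratios of the colours had an r of 0.05 and a rho of 0.07 across genes. The Y-linked list was the only one of 23 outside the middle 95% of matched random lists in the same direction in both colours, at percentiles 99.7 and 100. Fibroblast genes had a median male over female log2 ratio of -4.20 within GFP (percentile 0.26) and 0.56 within tdTomato (97.2). Mitochondrially encoded genes were at -1.77 (percentile 0.06) and 0.17 (93.0), and immediate early genes at -0.81 (4.48) and 0.31 (99.6). Of the sex steroid receptors, Esr1, the estrogen receptor, measured 0.08 CPM in female GFP, 152 CPM in male GFP, and 31.3 and 14.02 CPM in female and male tdTomato.

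Some X-linked genes that escape inactivation differed between the male libraries, in a library where 15.9% of all genes at 10 CPM or more in both tdTomato libraries had 0 counts (male GFP). Eif2s3x, Kdm5c and Kdm6a each had 0 counts in male GFP and stood at 58.3, 21.0 and 72.2 CPM in male tdTomato. In the female libraries Eif2s3x measured 74.8 and 88.8 CPM, Kdm5c 125 and 17.6 CPM, and Kdm6a 15.1 and 60.1 CPM in GFP and tdTomato. Ddx3x, of the same list, was at 1014 to 1805 CPM in all 4 libraries.

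The last comparison asked whether the difference between the colours differed between the sexes, for which 4 libraries left no test. Abhd13 was higher in GFP in the male pair (309 CPM against 0) and lower in GFP in the female pair (0.40 against 28.3 CPM). Smug1, a DNA repair glycosylase, Xrcc4, a factor of DNA end joining, the protocadherin Pcdh9 and the atypical cadherin Fat4 had the same pattern, at 145 to 222 CPM in male GFP. Kcnip4, a potassium channel partner, went the other way, at 114 CPM in female GFP against 0.135 CPM and at 0 in male GFP against 27.5 CPM, as did Pde8a, Zfp566 and Tmem135. In all, 2893 of 15055 genes had opposite folds of at least 2 in the pairs, 1167 higher in GFP in the male pair and 1726 higher in GFP in the female pair, against 1226 and 1658 if the pairs were independent.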

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

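The tests in this part that were chosen only after the result was seen are those on the endothelial and fibroblast lists and the loss by length class; the others on genes absent from both GFP libraries were fixed before their results were seen, but the rule written against random loss, a lower bound on a ratio, was met and then set aside once other divisions had been seen.

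Opposite differences between the colours in the female and male pairs drew attention to 9 genes reported here and 1 gene list, and none of these differences was tested, since each value rests on 4 libraries. The male minus female difference of the log2 GFP over tdTomato ratio was 16.60 for Abhd13, 16.41 for Smug1, 16.16 for Xrcc4, 15.997 for Fat4 and 15.86 for Pcdh9. It was -16.05 for Kcnip4, -15.60 for Pde8a, -15.50 for Zfp566 and -14.82 for Tmem135. These genes were picked for that difference, each is at or near 0 counts in at least 1 library, and the sizes depend on the prior count. The median of the immediate early and heat shock list differed by -1.32.

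Genes absent from GFP formed the first pattern. Of 6813 genes at 10 CPM or more in both tdTomato libraries, 642 were at 3 counts or fewer in female GFP, 1615 in male GFP and 373 in both. Random and separate loss in each GFP library would give 210.5 in both within classes of expression, a ratio of 1.77 (bootstrap 95% interval 1.66 to 1.88). The ratio alone does not exclude such loss, because divisions that follow neither colour nor sex also passed its bound, at 2.27 (1.66 to 2.81) and 4.28 (2.62 to 5.95), on only 18 and 14 genes. Annotated transcript length is argued against as the cause of the excess, since loss hardly followed it. Across 5 classes, from a median of 629 to 3706 nt, 4.98% to 6.28% of genes were absent from both, 8.41% to 11.3% from female GFP and 23.3% to 26.0% from male GFP. The ratio was accordingly 1.69 (1.59 to 1.79) within length classes and 1.70 without them. Loss that depends on other properties of a gene and a lower expression in GFP cells both stay open.

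The low endothelial list in GFP was the second pattern. Random loss of genes separately from each other is argued against. Of 15 members, 13 were at least 2-fold lower in both pairs against 1 to 8 in 95% of matched lists. None of the lists held as many, 0% against a bound of 0.109% for a list picked among 23. Matched lists cannot show joint loss of genes that share the same few cells, so such loss stays open. The list also did not pass with fry (adjusted p = 0.289) or with camera at an estimated correlation (adjusted p = 0.894). On 1 residual degree of freedom that camera test could hardly have passed, so it decides nothing. At their tdTomato level 15 of 15 members would have passed 3 counts in both GFP libraries, and 3 did. The filter on counts kept such genes, so the 15 could hardly have come out otherwise and decides nothing about depth. With absent genes set at 3 counts, the list's medians were -5.94 in the female pair and -4.60 in the male pair (log2). These medians allow for the depth of each GFP library and argue against lower depth, for the tested members. A low share of endothelial cells among GFP cells, which the sort by lineage would give, may account for it, and remains a hypothesis on the same data.

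Fibroblast genes, 10 of 15 of them lower in male GFP than in female GFP and 5 higher, were the third pattern, and the list's median was below tdTomato in female GFP too (-0.94, log2, percentile 2.18 of matched lists). Random loss in male GFP stays open, since the list's median of -4.20 (male over female, log2), at percentile 0.26 of matched lists, is what drew attention to it and is not below the bound of 0.109 for a list picked among 23. Spill of unselected tdTomato cells into female GFP would bring both lists at a like share of their tdTomato level. Endothelial genes reached a median of 0.289% (upper quartile 3.27%) and fibroblast genes 51.8% (lower quartile 25.3%). The shares speak against such spill, but both lists had been picked for these levels, so the comparison is no independent test. The quartile rule was written after a first rule on interquartile ranges had not decided, and spill of fibroblasts alone stays open. Loss in the male GFP library was not confined to markers. It had 79.3% as many genes with at least 10 counts as the next lowest library and 89.7% as many with at least 1. Of 144 subunit genes of complexes such as the proteasome and RNA polymerase II, 23.6% were at 3 counts or fewer there. All genes of like mean level gave 23.5%, and the subunits gave 2.78% in female GFP and 0.694% in each tdTomato library. For the fibroblast list, few cells behind male GFP and a difference of sex or animal cannot be told apart. The labels give no cell numbers and each sex was 1 suspension.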

How the results depend on the processing

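Chosen after the result was seen were the filter at 50 CPM, edgeR's newer and robust fits and the left-out libraries of the gene lists. The count of genes past the threshold between colours was 0 in edgeR under all scalings, filters and fits tried, with no replicate block, in limma-voom, and from 0 to 0 with each library left out and no block. DESeq2 gave 1157, and its calls for the other 2 divisions of the 4 libraries into pairs were 140 at most and 108 at least, 3 divisions being too few for a share under 0.05. Of the 20 genes named for the colours, 18 passed under DESeq2 and none under the other scaling or with no replicate block.

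Genes at least 2-fold apart within the female pair numbered 5867 with the filter of 5 CPM in 2 libraries and 5650 at 4-fold. Within tdTomato male and female differed for 3840 and 2758 genes, and in the same direction in both colours for 1610 and 954. Opposite folds were 1271 at 4-fold. Fewer genes or a larger fold produce these drops by construction. The other totals were within 1.5 times. By direction, genes higher in GFP in the male pair numbered 1739 at 4-fold against 3244, and genes higher in male within GFP 2566 against 4203.

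Of 5 gene lists past the threshold, 0 remained with fry, and 2 (endothelial and macrophage) remained with no filter. With an estimated correlation 0 remained, but 1 residual degree of freedom let hardly any list pass there. At a mean of 50 CPM 3 other lists passed (fibroblast, collagen and mitochondrial, all lower in GFP), none of the 5 did, and the endothelial, macrophage and Hox lists had too few genes there for a test. With no block 6 passed, the 5 and the fibroblast list. The fits with 1 library left out had no block either, so the sexes were not balanced between the colours, and calls gained or lost there can follow sex. Without female GFP 3 lists passed, of the 5 only smooth muscle, with fibroblast and mitochondrial genes (lower in GFP). Without male GFP 4 passed, endothelial, Hox and immediate early of the 5, with mitochondrial genes (higher in GFP). Without female tdTomato 5 passed, all of the 5 but the immediate early list, with fibroblast genes, and without male tdTomato 7, the 5 with fibroblast and Y-linked genes. The smooth muscle list turned lower in GFP at 50 CPM (adjusted p = 0.813), as did the immediate early list at 50 CPM (adjusted p = 0.110) and without female GFP (adjusted p = 0.499). The Y-linked call without male tdTomato follows from the sexes left in that fit. For the other lists the cause was not tested. By counting error alone, depth limits genes at 0 counts to bounds of 0.203 to 0.323 CPM, which do not cover loss of transcripts.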

Other observations

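The genes in this part were chosen after their values were seen unless the naming rule took them, and none was tested here.

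Some genes of cartilage were higher in female GFP than in the other libraries, and others were not. Cytl1, a secreted protein of cartilage, measured 4032 CPM in female GFP, 277 CPM in female tdTomato, 0.215 CPM in male GFP and 120 CPM in male tdTomato. Col2a1, the main collagen of cartilage, measured 90.6 CPM in female GFP and 0.405 to 0.968 CPM in the other libraries. Sox9, the transcription factor that drives cartilage formation, measured 151 CPM in female GFP, 0.215 CPM in male GFP, and 77.5 and 75.2 CPM in tdTomato. Col8a1, of the collagen list and not of the cartilage and bone list, measured 260 CPM in female GFP, 0 in male GFP, and 12.2 and 6.32 CPM in tdTomato. Acan measured 17.8 CPM in female GFP and 67.4 CPM in male GFP, and Fmod 9.52 CPM in female GFP against 30.1 CPM in female tdTomato. The cartilage and bone list had medians of 0.30 in the female pair (percentile 75.4 of matched lists) and -0.69 in the male pair, over 10 tested members. The filter left out members seen in 1 library only. Among them were Chad and Ibsp, with 4406 and 4573 counts in female GFP and 0 elsewhere. Spp1, with 373 counts in female tdTomato and 0 elsewhere, was left out too.

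Other genes set male GFP apart from the other libraries. Rgs5, a pericyte marker, measured 1707 CPM in male GFP and 295 to 500 CPM elsewhere, and Kcnj8, a potassium channel of the same cells, 67.5 CPM against 5.60 to 8.72 CPM. Other members of the pericyte list, which did not pass (adjusted p = 0.713), were mixed, Cspg4 at 296 CPM in male GFP against 128 to 173 CPM, Abcc9 at 96.9 against 78.96 to 151 CPM, Pdgfrb at 49.8 against 32.2 to 54.2 CPM, and Notch3 at 0 in both GFP libraries. Msx1 and Twist1, regulators of neural crest mesenchyme, measured 175 and 80.2 CPM in male GFP against 10.1 to 18.1 CPM and 4.56 to 10.1 CPM elsewhere. Heyl and Hey1, targets of Notch signalling, had 0 counts in male GFP and measured 129 and 36.2 CPM in female GFP, whereas Hes1, another target, measured 190 and 364 CPM. Whether these differences belong to the sex, the animals or the libraries was not tested, with 1 library on each side.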
